A study of Mus musculus with 15 samples.

How the data were processed

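RNA sequencing of liver total RNA from 15 wild-type mice was analysed, with 5 mice each on a control diet (Ctrl), an alcohol diet (Alc) and an alcohol diet with UA (Alc UA), per the labels. RNA was extracted with phenol and chloroform and libraries were made for an MGISEQ sequencer, per the labels' protocols. The authors deposited 1 table of FPKM values, with 18510 rows named by gene symbol and values given to 2 decimals. HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8, StringTie and DESeq are named in the submitters' processing notes, without their roles, and the genome build, the annotation and whether counting used strand are not given in the sources used here. Coordinates are therefore not printed. Reads of near-identical genes such as the Mup family, and of overlapping or antisense genes, could be split in ways that the table does not show. Columns were assigned to mice by the letter and number of their names (C, A and U with 1 to 5), matched to the sample titles. In 25 rows the gene symbol had been turned into a date, and 15 of these rows were tested but not named. A further 223 rows held 0 in every library.

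FPKM values are not counts, so no count model was used and the absolute depth of the libraries is unknown. Low values given to 2 decimals were too coarse to give the relative depth either, since the values that 1 read was worth came out the same in 11 of 15 libraries. Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 5 of 15 libraries were tested, 10959 in all. A weakly expressed gene could pass this filter through 1 group alone, so counts within lists with many untested members may favour 1 direction. A linear model over the 3 groups was fitted with limma 3.58.1 in R 4.3.3, with a mean trend in the variance prior, 12 residual degrees of freedom per gene and Benjamini-Hochberg adjustment at 0.05 within each comparison. The comparisons were Alc with Ctrl, Alc UA with Alc, and Alc UA with Ctrl. Each limma p-value sets a difference between groups against the spread between the mice sampled.

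Before the data were examined, 31 gene lists and 15 cell-type marker lists were fixed, of which 44 had genes to test. Each was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 44 lists. Camera with an estimated correlation and fry, which tests whether genes of a list move one way on balance, served as alternatives. The genes named in the text also followed a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 2 FPKM in the higher group and every library on its own side of the other group's mean. It added up to 4 genes with the smallest p from each list called, and 20 genes of alcohol metabolism, lipid metabolism, inflammation, fibrosis and stress whatever their p. The rule also covered up to 10 genes past the threshold with opposite signs in Alc against Ctrl and Alc UA against Alc. Predicted gene models were counted but not named. From this set, a part is printed, and 2 genes are not reported here.

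Comparisons that share libraries also share their chance values. Residuals of the fit were therefore permuted over libraries 100 times to give values without effects, and the shared libraries were divided 2 and 3 in 20 ways. Group labels of the 10 libraries of a comparison were redrawn in 100 of the 126 possible splits, the real one included, with the third group kept. Differences between 2 list means were compared between Alc and Ctrl with an exact permutation test over 252 assignments, 126 without Ctrl 5 and 56 without Ctrl 1 and Ctrl 5. The smallest p these can give is 0.0079, 0.0079 and 0.018, so counts of lists from the smaller fits are not directly comparable. Alternatives to the pseudocount, the filter, the scaling, the variance prior, library weights, the fold threshold, the libraries entering the fit and the replicate number as a block were computed, and each library was left out in turn. Fits without the libraries that stood apart were added after seeing the data.

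The fit was tested on simulated data with the means and residual spread of the real genes and 200 changed genes among 10959. For Alc against Ctrl it recovered 56% of genes changed by 0.5 on the log2 scale, 96% of those changed by 1, 98% by 2 and 100% by 3, and 6.91% of calls were false. For Alc UA against Alc it recovered 56%, 90%, 100% and 100%, and 3.35% of calls were false. Camera called 0 of 40 simulated unchanged lists of 20 genes in either comparison, in data simulated without correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.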

Results

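Messenger RNA was measured by RNA sequencing in the livers of 15 wild-type mice in 3 groups of 5. The Ctrl group received a control diet, the Alc group an alcohol diet, and the Alc UA group an alcohol diet together with UA, an abbreviation that the labels do not expand. Expression was given as FPKM, fragments mapped to a transcript scaled for its length and for the fragments mapped in the library, for 18510 rows. The FPKM values of a library summed to between 551153 and 668832, and between 10119 and 11471 genes reached 1 FPKM. The number of reads per library is unknown. In what follows, levels are mean FPKM ± SD (n = 5 libraries per group), and log2 fold changes are differences of log2(FPKM + 1) ± SE, a scale that understates the change of weakly expressed genes. In the comparisons with Ctrl, medians of lists are given relative to the median of all tested genes.

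The control livers lay apart from both alcohol groups on the first principal component, which held 45.7% of the variance, and the second held 14.0%. Ctrl 5 lay nearest to the alcohol libraries on the first component, at -6.04, while the other controls lay between -48.4 and -30.2. Ctrl 1 and Alc 4 had the highest scores on the second, at 23.2 and 25.1. Pearson correlations across genes, which are not independent replicates, were 0.960 to 0.990 within Ctrl, 0.975 to 0.992 within Alc and 0.972 to 0.986 within Alc UA. Between Ctrl and Alc they were 0.941 to 0.976.

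**Figure D1:**
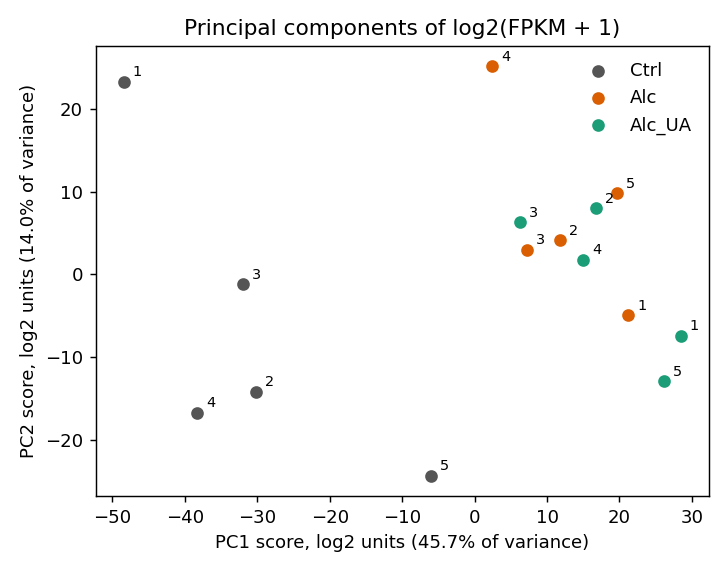
Scores of the 15 libraries on the first (horizontal) and second (vertical) principal component of log2(FPKM + 1) over 10959 genes, in log2 units. Colours mark the groups and numbers the replicates. All 10 alcohol libraries lie at scores above 0 on the first component and all 5 control libraries below 0.

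The comparison of Alc with Ctrl asks which transcripts differed in the liver on the alcohol diet. Genes of the circadian clock differed between the groups. Dbp, an output transcription factor of the clock, was 19.3-fold higher (83.3 ± 25.8 in Alc against 4.31 ± 1.38 in Ctrl; log2 fold change 3.98 ± 0.20, limma adjusted p = 1.2e-08). Per3, a repressor in the clock feedback loop, was 9.70 ± 3.22 in Alc against 0.792 ± 0.257 in Ctrl (log2 fold change 2.54 ± 0.17, limma adjusted p = 2.4e-07). Usp2 rose by 2.74 ± 0.18 and Ciart rose by 3.11 ± 0.25 on the log2 scale (adjusted p = 2.4e-07 and 1.7e-06). Arntl, which encodes the activator BMAL1, was lower (1.21 ± 0.194 in Alc against 9.74 ± 1.79 in Ctrl; log2 fold change -2.27 ± 0.12, limma adjusted p = 2.8e-08). Of the 20 clock genes tested, 13 rose and 4 fell over all genes tested, against 15 and 4 adjusted over the list alone (median 1.2, camera adjusted p = 2.8e-09; adjusted p = 0.035 with an estimated correlation). It was the list whose call held with an estimated correlation in this comparison. The time of day at which livers were collected is not given in the sources used here. A difference in it between the groups would bear on every gene and list compared with Ctrl, and this was not tested.

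In all, 3654 of 10959 genes changed (limma, Benjamini-Hochberg adjusted p under 0.05), 1157 higher and 2497 lower in Alc. Of these, 131 rose and 222 fell by more than 1 on the log2 scale. The median log2 fold change of all tested genes was -0.12. After quantile normalization, which brought that median to -0.0019, 2049 genes were higher and 2024 lower. With median-of-ratios size factors the split was 2012 and 1943, and with each library scaled to the same sum it was 1596 and 1273. Log2 fold changes of single genes were left on the deposited scale. With library weights 5870 genes passed. Camera called 21 of 44 lists, and as many were called in 27 of 100 splits of the 10 libraries, the real one included.

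Xenobiotic and ethanol metabolism genes were higher in Alc. Of 20 cytochrome P450 genes of drug metabolism, 13 rose and 0 fell over all genes tested, against 14 and 0 adjusted over the list alone (median 1.14, camera adjusted p = 3.6e-10; adjusted p = 0.060 with an estimated correlation). Cyp2b9 was 135 ± 85.2 in Alc against 1.31 ± 2.73 in Ctrl (log2 fold change 6.20 ± 0.75, limma adjusted p = 6.7e-05), and 1 control library, Ctrl 1, held 6.19 of it. Cyp2a5, which hydroxylates coumarin, was 762 ± 225 in Alc against 95 ± 97.9 in Ctrl (log2 fold change 3.48 ± 0.48, limma adjusted p = 1.9e-04). Por, the reductase that supplies electrons to these enzymes, rose by 1.27 ± 0.15 (adjusted p = 6.2e-05). Among 14 ethanol and acetaldehyde metabolism genes, 8 rose and 1 fell over all genes tested, against 9 and 1 adjusted over the list alone (median 0.57, camera adjusted p = 1.3e-06; adjusted p = 0.16 with an estimated correlation). Cyp2e1, the ethanol-inducible P450, was 2.0-fold higher (7727 ± 564 in Alc against 3869 ± 1016 in Ctrl; log2 fold change 1.04 ± 0.18, limma adjusted p = 8.8e-04). Aldh2, which oxidises acetaldehyde, rose by 0.70 ± 0.12 and Acss2, which activates acetate, rose by 0.93 ± 0.12 (adjusted p = 7.7e-04 and 1.0e-04). Adh1 rose by 0.56 ± 0.19 (adjusted p = 0.032), a call that ended without Ctrl 1 and Ctrl 5 (adjusted p = 0.096, chosen after seeing the data) and without any 1 of Ctrl 3, Ctrl 4, Ctrl 5, Alc 4 or Alc 5 (adjusted p = 0.052 to 0.080). Adh1 also lost the call without the filter, with the 2 groups alone, and with library weights (adjusted p = 0.052 to 0.10). Pericentral hepatocyte genes overlapped with these enzymes, and of 23 tested, 12 rose and 2 fell over all genes tested, against 13 and 2 adjusted over the list alone (median 0.65, camera adjusted p = 3.4e-05; adjusted p = 0.53 with an estimated correlation). For 10 AHR targets, 3 rose and 1 fell over all genes tested, against 3 and 1 adjusted over the list alone (median 0.19, camera adjusted p = 0.049; adjusted p = 0.64 with an estimated correlation). AHR targets lost the call without any 1 of Ctrl 3, Ctrl 4, Alc 4, Alc 5, Alc UA 1, Alc UA 2, Alc UA 3, Alc UA 4 or Alc UA 5 (adjusted p = 0.05003 to 0.14).

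Markers of sinusoidal endothelial cells were lower in Alc. Of 14 tested, 0 rose and 13 fell over all genes tested, against 0 and 13 adjusted over the list alone (median -1.16, camera adjusted p = 1.3e-06; adjusted p = 0.52 with an estimated correlation). Tek, an endothelial receptor kinase, was 2.07 ± 0.67 in Alc against 7.48 ± 2.28 in Ctrl (log2 fold change -1.45 ± 0.19, limma adjusted p = 1.1e-04). Dnase1l3 fell by 1.58 ± 0.24 and the lectin gene Clec4g fell by 1.71 ± 0.26 on the log2 scale (adjusted p = 3.5e-04 and 3.9e-04). Blood transcripts moved with them. Of 6 erythroid genes, 1 rose and 5 fell over all genes tested, against 1 and 5 adjusted over the list alone (median -2.01, camera adjusted p = 0.049; adjusted p = 0.64 with an estimated correlation). The globin Hba-a2 was 146 ± 42.2 in Alc against 817 ± 578 in Ctrl (log2 fold change -2.27 ± 0.40, limma adjusted p = 0.0010), and Hbb-bs was 260.4 ± 58.1 in Alc against 1417 ± 1099 in Ctrl. Car1, also on that list, rose by 0.75 ± 0.13 (adjusted p = 7.4e-04). T and NK cell markers gave 0 higher and 5 lower of 5, also 0 and 5 adjusted over the list alone (median -0.76, camera adjusted p = 0.049; adjusted p = 0.64 with an estimated correlation), with Ccl5 at 2.84 ± 1.79 in Alc against 11.5 ± 7.24 in Ctrl. B and plasma cell markers gave 0 higher and 4 lower of 5, also 0 and 4 adjusted over the list alone (median -0.85, camera adjusted p = 0.049; adjusted p = 0.64 with an estimated correlation), with Jchain at 1.40 ± 0.570 in Alc against 5.80 ± 2.41 in Ctrl. The T and NK list held 16 genes and the B and plasma list 12. Most failed the filter, which weakly expressed members could pass through Ctrl alone, so these counts may favour falls. Of 13 Kupffer cell markers, 0 passed over all genes or adjusted over the list alone (median 0.41, camera adjusted p = 0.034; adjusted p = 0.84 with an estimated correlation). Cd163, the Kupffer marker with the smallest p, was 0.56 ± 0.23 (adjusted p = 0.069). Cd163 passed after quantile normalization, with median-of-ratios size factors, with libraries scaled to the same sum, and with library weights (adjusted p = 0.015 to 0.039). The erythroid list lost the call without any 1 of Ctrl 1, Ctrl 3, Ctrl 5, Alc 1, Alc 3, Alc 4, Alc UA 2, Alc UA 4 or Alc UA 5 (adjusted p = 0.054 to 0.13). The T and NK cell list lost the call without any 1 of Ctrl 1, Ctrl 2, Ctrl 3, Ctrl 4, Alc 1, Alc 2, Alc 3, Alc 5, Alc UA 1, Alc UA 2, Alc UA 3, Alc UA 4 or Alc UA 5 (adjusted p = 0.05003 to 0.087). The B and plasma cell list lost the call without any 1 of Ctrl 1, Ctrl 4, Alc 1, Alc UA 2 or Alc UA 4 (adjusted p = 0.0504 to 0.079). The Kupffer list lost the call without any 1 of Ctrl 3, Ctrl 5 or Alc 2 (adjusted p = 0.086 to 0.19).

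**Figure D2:**
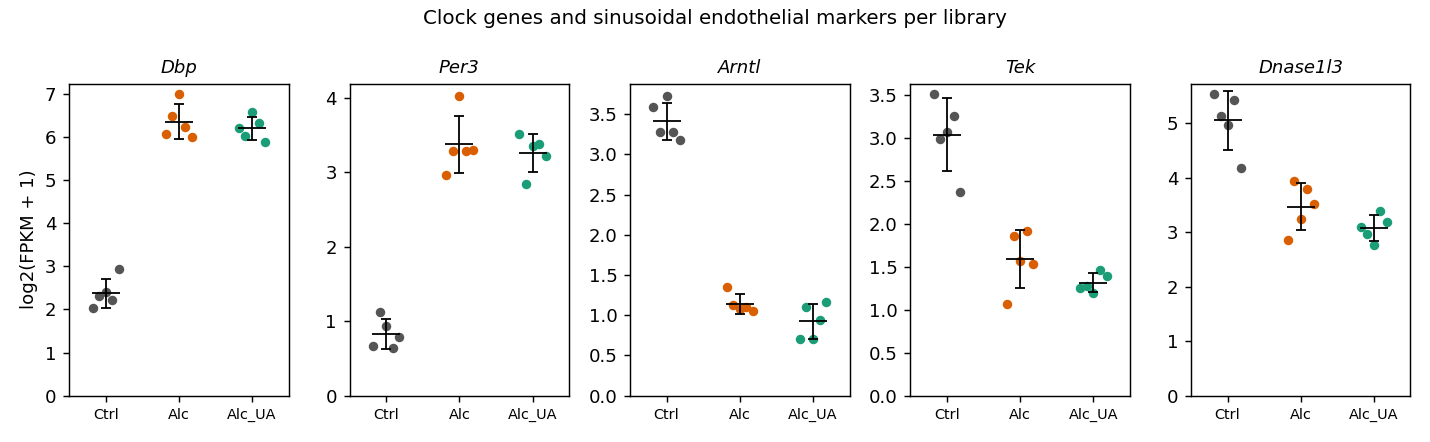
Expression of 3 clock genes and 2 sinusoidal endothelial markers in each library as log2(FPKM + 1). Points are libraries, horizontal bars are group means and whiskers are SD (n = 5 per group). For Dbp and Per3 every alcohol library lies above every control library, and for Arntl every one lies below.

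Genes whose expression differs between male and female mouse liver moved in opposite directions. Of 21 male-biased genes tested, 0 rose and 13 fell over all genes tested, against 0 and 15 adjusted over the list alone (median -1.23, camera adjusted p = 3.6e-04; adjusted p = 0.52 with an estimated correlation). Elovl3, a fatty acid elongase, was 22.6 ± 4.98 in Alc against 289 ± 92.9 in Ctrl (log2 fold change -3.58 ± 0.21, limma adjusted p = 6.7e-08). Mup21, a major urinary protein gene, was 67.3 ± 23.3 in Alc against 564 ± 154 in Ctrl (log2 fold change -3.08 ± 0.28, limma adjusted p = 5.5e-06), and reads shared among Mup genes make single Mup values uncertain. The complement gene C6 fell by 1.57 ± 0.27 and Cyp4a12b fell by 1.30 ± 0.27 (adjusted p = 8.0e-04 and 0.0025). Of the 7 female-biased genes tested, 5 rose and 0 fell over all genes tested, against 6 and 0 adjusted over the list alone (median 1.32, camera adjusted p = 1.1e-04; adjusted p = 0.12 with an estimated correlation). Besides Cyp2b9 they included the thioesterase gene Acot3 (1.71 ± 0.35, adjusted p = 0.0025). The list held 23 genes, and those low in Ctrl could pass the filter only by rising on alcohol. Cyp2b9 was such a gene, at 0.12 FPKM or less in controls other than Ctrl 1, so these counts may favour rises. Every library expressed the Y-linked gene Ddx3y, at 10.8 FPKM or more.

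Lipid and carbohydrate genes went both ways within their lists. Of 24 fatty acid and triglyceride synthesis genes, 9 rose and 3 fell over all genes tested, against 9 and 3 adjusted over the list alone (median 0.52, camera adjusted p = 0.0036; adjusted p = 0.58 with an estimated correlation). Thrsp, a lipogenic nuclear protein gene, was 87.5 ± 52.7 in Alc against 11.4 ± 6.70 in Ctrl (log2 fold change 2.72 ± 0.49, limma adjusted p = 0.0011). Dgat2, which makes triglyceride, rose by 1.10 ± 0.13, and Insig2, which retains SREBP in the endoplasmic reticulum, fell by 1.48 ± 0.23 (adjusted p = 5.3e-05 and 3.9e-04). For 24 cholesterol genes, 7 rose and 1 fell over all genes tested, against 7 and 1 adjusted over the list alone (median 0.53, camera adjusted p = 2.8e-05; adjusted p = 0.52 with an estimated correlation). For 30 gluconeogenesis, glycolysis and glycogen genes, 11 rose and 2 fell over all genes tested, against 11 and 2 adjusted over the list alone (median 0.45, camera adjusted p = 0.0013; adjusted p = 0.21 with an estimated correlation). Slc2a2, the hepatic glucose transporter, rose by 0.98 ± 0.13, and Ppp1r3c, which targets a phosphatase to glycogen, fell by 1.91 ± 0.27. Among 24 bile acid genes, 10 rose and 4 fell over all genes tested, against 10 and 5 adjusted over the list alone (median 0.43, camera adjusted p = 0.0018; adjusted p = 0.29 with an estimated correlation), with the uptake transporter gene Slc10a1, which rose by 0.91 ± 0.12.

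Amino acid catabolism and urea cycle genes gave 8 higher and 0 lower of 32, against 7 and 0 adjusted over the list alone (median 0.24, camera adjusted p = 0.0016; adjusted p = 0.64 with an estimated correlation). Of 26 methionine and one-carbon genes, 11 rose and 3 fell over all genes tested, against 11 and 3 adjusted over the list alone (median 0.38, camera adjusted p = 0.0055; adjusted p = 0.29 with an estimated correlation). In the NAD and sirtuin list of 27, 7 rose and 5 fell over all genes tested, against 8 and 5 adjusted over the list alone (median 0.22, camera adjusted p = 0.049; adjusted p = 0.64 with an estimated correlation), and its mean log2 fold change of -4.2e-04 and its median of 0.10 on the deposited scale differed in sign. Of 28 acute-phase genes, 6 rose and 2 fell over all genes tested, against 6 and 2 adjusted over the list alone (median 0.28, camera adjusted p = 0.049; adjusted p = 0.52 with an estimated correlation). Serpina3m rose by 1.67 ± 0.25, and Hamp, which encodes hepcidin, was 729 ± 483 in Alc against 2723 ± 1522 in Ctrl (log2 fold change -1.80 ± 0.48, limma adjusted p = 0.011). Ribosomal protein genes numbered 49, and 1 rose and 19 fell over all genes tested, against 1 and 27 adjusted over the list alone (median -0.22, camera adjusted p = 0.0036; adjusted p = 0.90 with an estimated correlation), with Rpl18, which fell by 0.61 ± 0.14. That count depended on scale, since with median-of-ratios size factors 1 rose and 4 fell. The NAD list lost the call without any 1 of Ctrl 1, Ctrl 3, Ctrl 4, Alc 1, Alc 2, Alc 3, Alc UA 1, Alc UA 2, Alc UA 3, Alc UA 4 or Alc UA 5 (adjusted p = 0.05003 to 0.10). The acute-phase list lost the call without any 1 of Ctrl 2, Ctrl 3, Alc 1, Alc 2, Alc UA 2 or Alc UA 4 (adjusted p = 0.0504 to 0.13). The ribosomal list lost the call without Ctrl 4 (adjusted p = 0.087).

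Among other genes, Rgs16, a regulator of G protein signalling, was 65.0 ± 26.2 in Alc against 4.04 ± 3.06 in Ctrl, and Upp2, a uridine phosphorylase gene, was 178 ± 30.4 in Alc against 27.6 ± 12.5 in Ctrl (adjusted p = 3.2e-05 and 3.0e-05). The heat-shock gene Hspa1a was 3.42 ± 4.26 in Alc against 41.5 ± 45.3 in Ctrl, Sco2, a cytochrome oxidase assembly gene, was 3.33 ± 1.47 in Alc against 33.9 ± 21.6 in Ctrl, and Cdkn1a, which encodes p21, was 3.97 ± 3.88 in Alc against 26.3 ± 8.47 in Ctrl (adjusted p = 0.0011, 5.2e-05 and 8.3e-04). Fasn rose by 0.55 ± 0.17 and the fatty acid transporter gene Cd36 rose by 1.27 ± 0.39, while Fgf21, a hepatic hormone gene, fell by 1.97 ± 0.56 (adjusted p = 0.022, 0.022 and 0.015). Fasn lost the call without any 1 of Ctrl 4, Alc 2, Alc 4 or Alc 5 (adjusted p = 0.051 to 0.063). Cd36 lost the call without any 1 of Ctrl 4, Alc 4 or Alc 5 (adjusted p = 0.053 to 0.063). The following did not pass: Cyp7a1 0.52 ± 0.43, Scd1 0.41 ± 0.55, Cpt1a 0.35 ± 0.15, Plin2 -0.70 ± 0.27, Saa1 0.68 ± 0.86, Lcn2 1.30 ± 0.63, Ccl2 -0.04 ± 0.42, Col1a1 0.04 ± 0.33, Nqo1 0.71 ± 0.29, Hmox1 -0.36 ± 0.40, Pink1 0.02 ± 0.08 and Sirt1 -0.18 ± 0.11 (log2 fold changes; adjusted p from 0.058 to 0.95). Saa1 reached 501.9 FPKM in Ctrl 1. Cpt1a passed without any 1 of Ctrl 5 or Alc 3 (adjusted p = 0.029 to 0.0499), and it passed after quantile normalization, with median-of-ratios size factors, with libraries scaled to the same sum, and with library weights (adjusted p = 0.017 to 0.049). Plin2 passed without any 1 of Ctrl 1, Alc 4 or Alc UA 2 (adjusted p = 0.023 to 0.0497), and it passed with the 2 groups alone and with library weights (adjusted p = 0.0087 to 0.046). Lcn2 passed without Ctrl 1 (adjusted p = 0.014), and it passed with library weights and without Ctrl 1 and Ctrl 5 (adjusted p = 0.0016 to 0.032; the last chosen after seeing the data). Nqo1 passed without any 1 of Ctrl 1 or Alc 2 (adjusted p = 0.025 to 0.026), and it passed after quantile normalization, with median-of-ratios size factors, with libraries scaled to the same sum, and without Ctrl 1 and Ctrl 5 (adjusted p = 0.017 to 0.049; the last chosen after seeing the data). Sirt1 passed with library weights (adjusted p = 0.031). Tnf, at 0.116 ± 0.0541 in Alc and 0.496 ± 0.506 in Ctrl, and Cyp1a1, at 0.184 ± 0.0611 and 0.114 ± 0.0619, were too low to be tested.

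The remaining lists were not called in Alc against Ctrl. Their counts of genes higher and lower over all genes tested, then adjusted over the list alone, follow. For ER stress and integrated stress response they were 5 and 5, then 5 and 5, of 28, and for immediate-early and dissociation stress genes they were 0 and 8, then 0 and 8, of 24. For fatty acid oxidation and PPARA targets they were 6 and 4, then 6 and 4, of 37, and for autophagy and mitophagy they were 5 and 3, then 1 and 2, of 32. For retinol metabolism they were 5 and 5, then 6 and 5, of 21, and for dendritic cell and antigen presentation they were 0 and 1, then 0 and 1, of 8. For platelet and megakaryocyte they were 0 and 1, then 0 and 2, of 2, and for inflammatory cytokines and NF-kB targets they were 1 and 4, then 0 and 0, of 24. For neutrophil they were 0 and 1, then 0 and 1, of 4, and for stellate cell they were 0 and 2, then 0 and 0, of 15. For mesothelial cell they were 0 and 1, then 0 and 1, of 2, and for p53 targets and cell death they were 2 and 10, then 3 and 10, of 25. For NRF2 targets and antioxidant defence they were 1 and 4, then 1 and 3, of 38, and for nuclear-encoded oxidative phosphorylation they were 7 and 18, then 7 and 19, of 57. For cell cycle and DNA replication they were 0 and 1, then 0 and 1, of 16, and for periportal hepatocyte genes they were 3 and 2, then 2 and 2, of 23. For cholangiocyte they were 0 and 1, then 0 and 1, of 7, and for adipocyte they were 1 and 1, then 1 and 1, of 5. For lipid droplet and fatty acid uptake they were 4 and 8, then 4 and 9, of 26, and for interferon-stimulated genes they were 2 and 3, then 0 and 2, of 33. For hepatocyte they were 2 and 4, then 3 and 4, of 14, and for extracellular matrix and fibrogenesis they were 1 and 2, then 1 and 1, of 22. For monocyte and recruited macrophage they were 0 and 1, then 0 and 1, of 10. Camera adjusted p ranged from 0.10 to 0.94. With median-of-ratios size factors the oxidative phosphorylation count over all genes became 13 higher and 8 lower. The lists of mitochondrially encoded transcripts and of pancreatic acinar cell had 0 genes tested.

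The comparison of Alc UA with Alc asks what UA changed on the alcohol diet. Male-biased liver genes were higher in Alc UA as a group. Of 21 tested, 0 passed over all genes and 14 rose adjusted over the list alone, with 0 lower and a median log2 fold change of 1.11 (camera adjusted p = 7.4e-29; adjusted p = 0.016 with an estimated correlation). C6 was 60.2 ± 18.4 in Alc UA against 20.6 ± 8.23 in Alc (log2 fold change 1.55 ± 0.27, limma adjusted p = 0.092), and Cyp4a12b was 66.5 ± 26.2 in Alc UA against 25.2 ± 7.75 in Alc (log2 fold change 1.32 ± 0.27, limma adjusted p = 0.20). Mup21 was 198 ± 66.8 in Alc UA against 67.3 ± 23.3 in Alc and Mup1 1316 ± 485 in Alc UA against 183 ± 114 in Alc (adjusted p = 0.11 and 0.12). C6 passed without any 1 of Ctrl 1 or Alc UA 4 (adjusted p = 0.042 to 0.048), and it passed with library weights (adjusted p = 0.026). Cyp4a12b passed without Alc UA 4 (adjusted p = 0.037). Mup21 passed without Alc UA 4 (adjusted p = 0.037). Transcripts of all Mup genes made up 18.6% ± 4.24 of FPKM in Alc UA, 9.71% ± 3.87 in Alc and 11.5% ± 1.96 in Ctrl (SD, n = 5). Without the Mup genes, 21 became 16 genes with a median of 0.78, all 16 with positive log2 fold changes and 10 higher adjusted over the list alone (camera adjusted p = 1.2e-19; adjusted p = 0.024 with an estimated correlation, chosen after seeing the data).

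Mup5 was the 1 gene of 10959 that changed, at 19.3 ± 9.81 in Alc UA against 2.82 ± 0.832 in Alc (log2 fold change 2.29 ± 0.28, limma adjusted p = 0.0041). Unadjusted limma p was under 0.05 for 664 of 10959 genes, near the share of 0.05 that chance alone gives. The Mup5 call ended without Alc 4 and Alc UA 2, libraries that stand apart on principal components (adjusted p = 0.10, chosen after seeing the data), and 0 genes were then called. It also ended when the fit held the 2 groups alone (adjusted p = 0.091) and when the replicate number entered as a block. The count was 5 without Alc UA 4, 4 without Ctrl 1, and 2 without any 1 of Ctrl 3, Alc 1 or Alc UA 1. Over all its alternatives the adjusted p of Mup5 was 3.4e-05 to 0.10. Mup5 shares sequence with its paralogs, so reads assigned to it are uncertain.

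**Figure D3:**
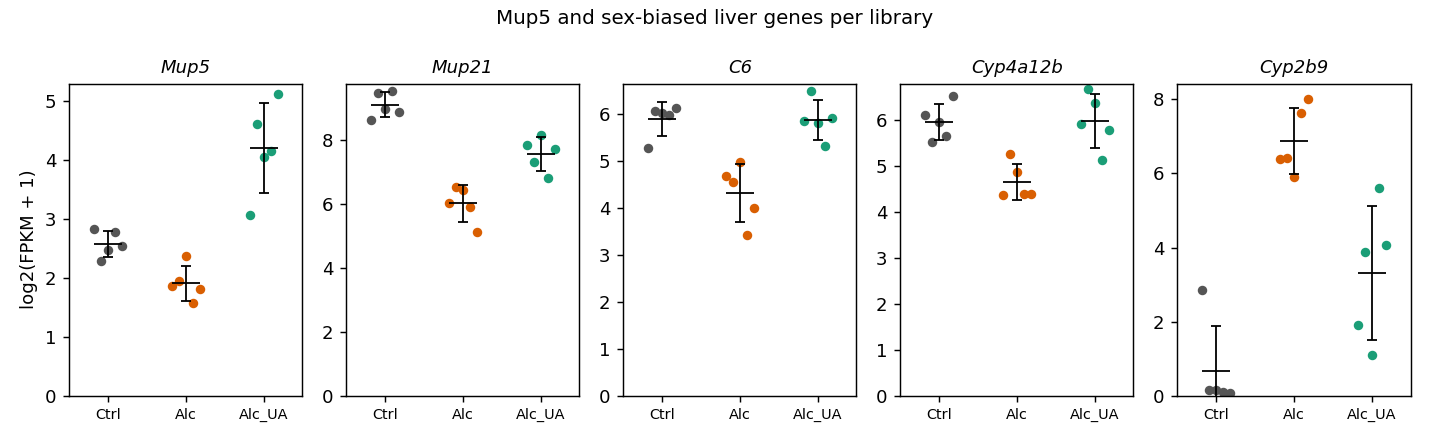
Expression of Mup5, 3 male-biased genes (Mup21, C6, Cyp4a12b) and the female-biased gene Cyp2b9 in each library as log2(FPKM + 1). Points are libraries, horizontal bars are group means and whiskers are SD (n = 5 per group). Every Alc UA library lies above every Alc library for Mup5, Mup21 and C6.

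Camera called 10 of 44 lists in this comparison, and as many were called in 88 of 100 splits of the 10 libraries. Apart from the male-biased list, each call was lost with an estimated correlation, and 0 members passed over all genes. Female-biased genes had a median of -0.37 with 1 of 7 lower adjusted over the list alone (camera adjusted p = 0.0081; adjusted p = 0.84 with an estimated correlation). Cyp2b9 was 16.2 ± 18.7 in Alc UA against 135 ± 85.2 in Alc (log2 fold change -3.56 ± 0.75, limma adjusted p = 0.23), and Cyp17a1, a steroid hydroxylase gene, was -1.14 ± 0.45. P450 genes of drug metabolism had a median of -0.19 with 4 of 20 lower adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.85 with an estimated correlation), and Cyp3a59 was 23.0 ± 6.45 in Alc UA against 47.2 ± 6.38 in Alc (log2 fold change -1.03 ± 0.22, limma adjusted p = 0.23). Oxidative phosphorylation genes had a median of -0.17 (camera adjusted p = 3.1e-06; adjusted p = 0.85 with an estimated correlation), with Ndufb10 at -0.29 ± 0.13. Cholesterol genes had a median of -0.30 (camera adjusted p = 4.9e-05; adjusted p = 0.85 with an estimated correlation), with Sqle at -0.71 ± 0.21. Retinol metabolism genes had a median of -0.24 with 2 of 21 lower adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.84 with an estimated correlation), with Ttr at -0.54 ± 0.16. Sinusoidal endothelial markers had a median of -0.40 (camera adjusted p = 1.7e-04; adjusted p = 0.85 with an estimated correlation), with Oit3 at -0.56 ± 0.25. The female-biased list lost the call without any 1 of Alc 1, Alc 5, Alc UA 2 or Alc UA 3 (adjusted p = 0.054 to 0.10). The P450 list lost the call without any 1 of Alc 1, Alc 5, Alc UA 2, Alc UA 3 or Alc UA 4 (adjusted p = 0.060 to 0.23).

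Fatty acid oxidation genes had a median of 0.11 in Alc UA against Alc (camera adjusted p = 4.9e-05; adjusted p = 0.85 with an estimated correlation), with Cyp4a10 at 0.25 ± 0.14. The fatty acid oxidation list lost the call without Alc 3 (adjusted p = 0.059). The median was 0.15 for immediate-early genes (camera adjusted p = 7.7e-04; adjusted p = 0.85 with an estimated correlation), with Nr4a1 at 1.36 ± 0.63, and 0.08 for inflammatory cytokine genes (camera adjusted p = 0.0027; adjusted p = 0.88 with an estimated correlation), with Cd14 at 0.73 ± 0.25. In these 3 lists and in the oxidative phosphorylation, cholesterol and endothelial lists, 0 genes passed adjusted over the list alone. Clock genes had a median of -0.12, and 0 of 20 passed over all genes or adjusted over the list alone (camera adjusted p = 0.90). Other genes named in advance did not pass (limma adjusted p of 0.51 to 0.97). Their log2 fold changes were Cyp2e1 0.19 ± 0.18, Adh1 -0.24 ± 0.19, Aldh2 -0.14 ± 0.12, Cyp7a1 -0.18 ± 0.43, Fasn -0.65 ± 0.17, Scd1 -0.57 ± 0.55, Cpt1a 0.24 ± 0.15, Plin2 0.23 ± 0.27, Cd36 -0.28 ± 0.39, Fgf21 0.56 ± 0.56, Saa1 0.24 ± 0.86, Lcn2 -0.49 ± 0.63, Ccl2 0.26 ± 0.42, Col1a1 -0.25 ± 0.33, Nqo1 -0.39 ± 0.29, Hmox1 0.87 ± 0.40, Pink1 0.04 ± 0.08 and Sirt1 0.03 ± 0.11. The remaining 34 lists had 0 genes past the threshold over all genes, 10 adjusted over the list alone (0 higher and 1 lower in fatty acid and triglyceride synthesis; 0 higher and 2 lower in bile acid synthesis and transport; 2 higher and 3 lower in gluconeogenesis, glycolysis and glycogen; 0 higher and 1 lower in amino acid catabolism and urea cycle; 0 higher and 1 lower in periportal hepatocyte genes), and camera adjusted p of 0.098 to 0.99.

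Whether UA moved the alcohol-diet changes back was examined from genes past the threshold in both Alc against Ctrl and Alc UA against Alc. There were 0 such genes with opposite signs and 0 with the same sign, at limma adjusted p under 0.05, against 4927 and 664 genes at an unadjusted p under 0.05 in the 2 comparisons. Of 10959 genes, 664 is near the share of 0.05 that chance alone gives. Since 1 gene, Mup5, passed in Alc UA against Alc, at most 1 could have met this rule. The 0 therefore cannot show that nothing moved back. Mup5 was 2.82 ± 0.832 in Alc and 5.03 ± 0.915 in Ctrl (adjusted p = 0.072). Every Alc UA library held 7.38 FPKM of it or more, above the highest control at 6.08, so its rise went past the Ctrl level. Leaving out 1 library gave 0 to 4 genes with opposite signs. There were 4 without Alc UA 4 (Mup12, chosen after its values were seen, Cyp4a12b, Mup21 and C6), 3 without Ctrl 1, and 1 without any 1 of Ctrl 3, Alc 1, Alc 3, Alc UA 1 or Alc UA 5. Without Alc 3, Alc UA 1 or Alc UA 5 the gene counted was Mup5, which went past Ctrl rather than back to it. Across genes, the log2 fold changes of the 2 comparisons had a Pearson correlation of -0.12, against -0.46 (range -0.85 to 0.02) in 100 simulations without effects in which the Alc libraries were likewise shared. The simulations lack the real differences of Alc against Ctrl, which widen its fold changes and so shrink the correlation in size. The observed and simulated correlations are therefore not comparable. The covariance, which is not divided by these spreads, was -0.0107, against -0.0139 simulated. With the Alc libraries divided so that none was shared, in 20 ways, the correlation averaged -0.0040 and ranged from -0.26 to 0.13. Among lists, male-biased genes were lower in Alc than in Ctrl (13 of 21 over all genes). They were higher in Alc UA than in Alc (14 of 21 adjusted over the list alone) and not called in Alc UA against Ctrl. The fall was not called with an estimated correlation, and sharing the Alc libraries favours opposite moves by chance. Elovl3 of that list stayed lower in Alc UA than in Ctrl (log2 fold change -3.23). Cholesterol, P450 and female-biased genes were called higher in Alc than in Ctrl (camera adjusted p = 2.8e-05, 3.6e-10 and 1.1e-04). They were called lower in Alc UA than in Alc (camera adjusted p = 4.9e-05, 0.026 and 0.0081). None of these calls held with an estimated correlation, and these lists were still called higher in Alc UA than in Ctrl. The endothelial list was lower in Alc than in Ctrl and lower again in Alc UA.

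The comparison of Alc UA with Ctrl asks which transcripts differed from the control diet when UA was given with alcohol. Clock genes differed here too, with Dbp at 73.3 ± 14.1 in Alc UA against 4.31 ± 1.38 in Ctrl (log2 fold change 3.82 ± 0.20, limma adjusted p = 1.1e-08) and Arntl at 0.912 ± 0.282 in Alc UA against 9.74 ± 1.79 in Ctrl (log2 fold change -2.49 ± 0.12, limma adjusted p = 1.1e-08). Of 20 tested, 14 rose and 4 fell over all genes tested, against 14 and 4 adjusted over the list alone (median 1.21, camera adjusted p = 8.3e-09; adjusted p = 0.038 with an estimated correlation), the list whose call held with an estimated correlation here. Sinusoidal endothelial markers were lower. Of 14, 0 rose and 14 fell over all genes tested, against 0 and 14 adjusted over the list alone (median -1.55, camera adjusted p = 2.0e-07; adjusted p = 0.49 with an estimated correlation), with Tek at 1.49 ± 0.191 in Alc UA against 7.48 ± 2.28 in Ctrl and Dnase1l3 at 7.58 ± 1.38 in Alc UA against 33.9 ± 11.2 in Ctrl. Of 13 Kupffer markers, 1 rose over all genes tested and 0 adjusted over the list alone (median 0.53, camera adjusted p = 0.0067; adjusted p = 0.90 with an estimated correlation). That gene, Cd5l, reached 210.4 FPKM in Alc UA 3 (log2 fold change 1.22 ± 0.46, adjusted p = 0.044). Cd5l lost the call without any 1 of Ctrl 2, Ctrl 3, Ctrl 4, Ctrl 5, Alc 2, Alc 5, Alc UA 3, Alc UA 4 or Alc UA 5 (adjusted p = 0.0505 to 0.10). Cd5l also lost the call without the filter, with the 2 groups alone, and with a robust prior (adjusted p = 0.054 to 0.077). The Kupffer list lost the call without Ctrl 5 (adjusted p = 0.0504). The globin Hba-a1 was 171 ± 91.9 in Alc UA against 1373 ± 974 in Ctrl (log2 fold change -2.85 ± 0.39, limma adjusted p = 1.2e-04).

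In this comparison 4673 genes changed (limma adjusted p under 0.05), 1152 higher and 3521 lower, of which 117 rose and 331 fell by more than 1 on the log2 scale. The median of all genes was -0.16, and the split became 2420 higher and 2430 lower after quantile normalization, 2425 and 2362 with median-of-ratios size factors, and 1316 and 2543 with libraries scaled to the same sum. Camera called 19 of 44 lists, and as many were called in 38 of 100 splits. After quantile normalization 7 lists were called.

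The P450 list had 11 higher and 0 lower of 20, also 11 and 0 adjusted over the list alone (median 0.90, camera adjusted p = 6.4e-07; adjusted p = 0.24 with an estimated correlation). Por rose by 1.58 ± 0.15, Cyp2a5 was 516 ± 149.9 in Alc UA against 95 ± 97.9 in Ctrl, and Cyp2b9 was 16.2 ± 18.7 in Alc UA against 1.31 ± 2.73 in Ctrl (adjusted p = 7.2e-06, 4.0e-04 and 0.011). For 14 ethanol metabolism genes, 5 rose and 1 fell over all genes tested, against 5 and 1 adjusted over the list alone (median 0.55, camera adjusted p = 4.3e-05; adjusted p = 0.35 with an estimated correlation), with Cyp2e1 at 8833 ± 1055 in Alc UA against 3869 ± 1016 in Ctrl (log2 fold change 1.23 ± 0.18, limma adjusted p = 1.9e-04) and Aldh2, which rose by 0.56 ± 0.12. For 23 pericentral genes, 11 rose and 2 fell over all genes tested, against 13 and 2 adjusted over the list alone (median 0.61, camera adjusted p = 5.6e-06; adjusted p = 0.49 with an estimated correlation). AHR targets gave 3 higher and 1 lower of 10, against 4 and 1 adjusted over the list alone (median 0.49, camera adjusted p = 0.013; adjusted p = 0.52 with an estimated correlation). AHR targets lost the call without Ctrl 3 (adjusted p = 0.056). Male-biased genes gave 1 higher and 3 lower of 21, against 1 and 2 adjusted over the list alone, and were not called (camera adjusted p = 0.70). Elovl3 was 29.2 ± 6.51 in Alc UA against 289 ± 92.9 in Ctrl (log2 fold change -3.23 ± 0.21, limma adjusted p = 3.2e-07). Mup17 was 3653 ± 2015 in Alc UA against 431 ± 312 in Ctrl and Mup16 2841 ± 629 in Alc UA against 500.2 ± 241 in Ctrl (adjusted p = 5.2e-04 and 7.6e-04), with the same uncertainty for Mup paralogs. Female-biased genes gave 4 higher and 1 lower of 7, also 4 and 1 adjusted over the list alone (median 1.17, camera adjusted p = 0.011; adjusted p = 0.35 with an estimated correlation).

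Of 57 nuclear-encoded oxidative phosphorylation genes, 4 rose and 37 fell over all genes tested, against 7 and 39 adjusted over the list alone (median -0.26, camera adjusted p = 0.026; adjusted p = 0.98 with an estimated correlation). Cycs, which encodes cytochrome c, was 41.2 ± 6.90 in Alc UA against 78.6 ± 18.5 in Ctrl, and Ndufa5 of complex I was 108 ± 17.5 in Alc UA against 217 ± 64.1 in Ctrl (adjusted p = 7.4e-04 and 8.4e-04). Of 49 ribosomal protein genes, 0 rose and 33 fell over all genes tested, against 0 and 34 adjusted over the list alone (median -0.26, camera adjusted p = 0.0046; adjusted p = 0.96 with an estimated correlation), with Rpl18, which fell by 0.65 ± 0.14. With median-of-ratios size factors these counts became 9 higher and 24 lower, and 1 higher and 8 lower. In the fatty acid oxidation list of 37, 8 rose and 2 fell over all genes tested, against 7 and 1 adjusted over the list alone (median 0.19, camera adjusted p = 0.011; adjusted p = 0.90 with an estimated correlation). Ppara, the nuclear receptor that regulates these genes, was 76.1 ± 10.8 in Alc UA against 39.9 ± 7.66 in Ctrl (log2 fold change 0.93 ± 0.14, limma adjusted p = 2.4e-04), and Cpt1a rose by 0.60 ± 0.15. Fatty acid synthesis genes gave 8 higher and 5 lower of 24, against 8 and 6 adjusted over the list alone (median 0.37, camera adjusted p = 0.026; adjusted p = 0.90 with an estimated correlation), with the elongase gene Elovl5, which fell by 1.16 ± 0.22. Cholesterol genes gave 6 higher and 3 lower of 24, also 6 and 3 adjusted over the list alone (median 0.18, camera adjusted p = 0.026; adjusted p = 0.90 with an estimated correlation), with Hmgcs1, which fell by 1.10 ± 0.22. Glucose and glycogen genes gave 8 higher and 4 lower of 30, also 8 and 4 adjusted over the list alone (median 0.28, camera adjusted p = 0.0046; adjusted p = 0.35 with an estimated correlation). Gys2, the liver glycogen synthase gene, was 204 ± 69.7 in Alc UA against 77.5 ± 15 in Ctrl, and Ppp1r3c was 5.41 ± 3.09 in Alc UA against 33.2 ± 10.7 in Ctrl (adjusted p = 2.2e-04 and 2.7e-05). The oxidative phosphorylation list lost the call without any 1 of Ctrl 4, Ctrl 5 or Alc UA 5 (adjusted p = 0.060 to 0.11). The ribosomal list lost the call without Ctrl 4 (adjusted p = 0.054). The fatty acid oxidation list lost the call without Ctrl 1 (adjusted p = 0.10). The fatty acid synthesis list lost the call without any 1 of Ctrl 1, Ctrl 3 or Alc UA 5 (adjusted p = 0.056 to 0.10). The cholesterol list lost the call without any 1 of Ctrl 1, Ctrl 3, Alc UA 1 or Alc UA 5 (adjusted p = 0.072 to 0.12).

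ER stress genes gave 5 higher and 3 lower of 28, also 5 and 3 adjusted over the list alone (median 0.36, camera adjusted p = 0.020; adjusted p = 0.64 with an estimated correlation). Herpud1, of endoplasmic reticulum protein degradation, rose by 1.28 ± 0.19 and the transcription factor gene Atf5 fell by 1.34 ± 0.21 (adjusted p = 2.2e-04 and 3.1e-04). Bile acid genes gave 8 higher and 2 lower of 24, also 8 and 2 adjusted over the list alone (median 0.27, camera adjusted p = 0.0045; adjusted p = 0.35 with an estimated correlation). One-carbon genes gave 10 higher and 5 lower of 26, also 10 and 5 adjusted over the list alone (median 0.33, camera adjusted p = 0.013; adjusted p = 0.37 with an estimated correlation), and their mean of -0.04 and median of 0.17 on the deposited scale differed in sign. Amino acid catabolism genes gave 6 higher and 1 lower of 32, against 2 and 0 adjusted over the list alone (median 0.22, camera adjusted p = 0.013; adjusted p = 0.90 with an estimated correlation). Acute-phase genes gave 6 higher and 4 lower of 28, against 6 and 3 adjusted over the list alone (median 0.24, camera adjusted p = 0.022; adjusted p = 0.37 with an estimated correlation). Hspa1a was 1.49 ± 0.949 in Alc UA against 41.5 ± 45.3 in Ctrl, and Maff, a small Maf transcription factor gene, was 16.4 ± 12.9 in Alc UA against 1.45 ± 0.328 in Ctrl (adjusted p = 2.4e-04 and 5.5e-04). The following did not pass: Adh1 0.32 ± 0.19, Cyp7a1 0.34 ± 0.43, Fasn -0.10 ± 0.17, Scd1 -0.17 ± 0.55, Plin2 -0.47 ± 0.27, Cd36 1.0 ± 0.39, Fgf21 -1.41 ± 0.56, Saa1 0.92 ± 0.86, Lcn2 0.81 ± 0.63, Ccl2 0.22 ± 0.42, Col1a1 -0.22 ± 0.33, Nqo1 0.32 ± 0.29, Hmox1 0.51 ± 0.40, Pink1 0.06 ± 0.08 and Sirt1 -0.15 ± 0.11 (log2 fold changes; limma adjusted p from 0.052 to 0.82). Adh1 passed with median-of-ratios size factors (adjusted p = 0.031). Plin2 passed without Alc UA 2 (adjusted p = 0.045). Cd36 passed without any 1 of Ctrl 1, Alc 1, Alc 3 or Alc 4 (adjusted p = 0.0050 to 0.048), and it passed with a mean of at least 5 FPKM, after quantile normalization, with median-of-ratios size factors, with libraries scaled to the same sum, with the 2 groups alone, with library weights, and without Ctrl 1 and Ctrl 5 (adjusted p = 0.0037 to 0.049; the last chosen after seeing the data). Fgf21 passed without any 1 of Ctrl 5, Alc 3, Alc 4 or Alc UA 2 (adjusted p = 0.011 to 0.040), and it passed with a pseudocount of 5, with the 2 groups alone, with library weights, and without Ctrl 1 and Ctrl 5 (adjusted p = 0.015 to 0.036; the last chosen after seeing the data). Saa1 passed without Ctrl 1 (adjusted p = 0.034), and it passed with library weights (adjusted p = 0.029). Lcn2 passed without Ctrl 1 (adjusted p = 0.041), and it passed with library weights (adjusted p = 0.021). Pink1 passed with median-of-ratios size factors (adjusted p = 0.033). The ER stress list lost the call without any 1 of Ctrl 3 or Alc UA 5 (adjusted p = 0.072 to 0.10). The amino acid list lost the call without Alc UA 1 (adjusted p = 0.071). The acute-phase list lost the call without any 1 of Ctrl 3 or Alc UA 5 (adjusted p = 0.072 to 0.074).

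In Alc UA against Ctrl, lists not called had counts of genes higher and lower over all genes tested, then adjusted over the list alone, as follows. For erythroid cell they were 1 and 5, then 1 and 5, of 6, and for B and plasma cell they were 0 and 4, then 0 and 4, of 5. For autophagy and mitophagy they were 2 and 4, then 0 and 2, of 32, and for NAD metabolism and sirtuins they were 8 and 7, then 8 and 7, of 27. For T and NK cell they were 0 and 4, then 0 and 5, of 5, and for cholangiocyte they were 0 and 3, then 0 and 3, of 7. For lipid droplet and fatty acid uptake they were 4 and 7, then 5 and 7, of 26, and for dendritic cell and antigen presentation they were 0 and 2, then 0 and 2, of 8. For stellate cell they were 0 and 3, then 0 and 3, of 15, and for male-biased liver genes they were 1 and 3, then 1 and 2, of 21. For adipocyte they were 1 and 2, then 1 and 2, of 5, and for inflammatory cytokines and NF-kB targets they were 1 and 4, then 1 and 0, of 24. For cell cycle and DNA replication they were 0 and 3, then 0 and 1, of 16, and for p53 targets and cell death they were 1 and 9, then 1 and 9, of 25. For periportal hepatocyte genes they were 2 and 3, then 1 and 1, of 23, and for monocyte and recruited macrophage they were 0 and 1, then 0 and 1, of 10. For platelet and megakaryocyte they were 0 and 0, then 0 and 0, of 2, and for extracellular matrix and fibrogenesis they were 1 and 2, then 1 and 2, of 22. For interferon-stimulated genes they were 0 and 8, then 0 and 7, of 33, and for retinol metabolism they were 2 and 7, then 2 and 7, of 21. For NRF2 targets and antioxidant defence they were 0 and 5, then 0 and 1, of 38, and for hepatocyte they were 1 and 5, then 1 and 5, of 14. For mesothelial cell they were 0 and 1, then 0 and 1, of 2, and for immediate-early and dissociation stress genes they were 0 and 7, then 0 and 6, of 24. For neutrophil they were 0 and 0, then 0 and 0, of 4. Camera adjusted p ranged from 0.091 to 0.98.

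Both comparisons with Ctrl called 859 genes higher and 2306 genes lower, and 0 genes in opposite directions. Independent lists of these lengths would share 121.6 higher and 802.3 lower genes. With unchanged simulated groups against shared controls, 0 or 1 gene was called in both. The log2 fold changes of the 2 comparisons had a Pearson correlation of 0.89 across genes, against 0.51 in the simulations (range -0.14 to 0.82). The covariance was 0.178, against 0.0167 simulated. With the Ctrl libraries divided so that none was shared, the correlation was 0.68 to 0.82, the covariance averaged 0.161, and 478 to 1994 genes were called in both with the same sign.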

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

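The tests of explanations in this part were chosen after the results they bear on were seen, except the counts of splits, which were fixed in advance. A library was listed where its gap to the nearest of its group passed the critical share of the group's range in Dixon's test, which chance gives in about 1 of 20 groups. Of 270 groups examined, 18 met this rule. Values are FPKM, judged on the log2(FPKM + 1) scale. In Ctrl 1, Saa1 was 502 (nearest 28.2), Cyp2b9 6.19 (nearest 0.120), Car1 3.34 (nearest 2.14) and C6 37.7 (nearest 62.8). Ctrl 5 had Cd163 at 0.630 (nearest 2.84), Jchain at 1.90 (nearest 5.83) and Maff at 0.890 (nearest 1.48). Alc 4 had Ccl2 at 5.00 (nearest 0.890), Cycs at 60.7 (nearest 43.5), Hspa1a at 11 (nearest 2.17) and Mup16 at 319 (nearest 1409). Arntl was 1.55 (nearest 1.18) in Alc 1. In Alc UA 2, Cd163 was 1.99 (nearest 3.53) and Insig2 139 (nearest 67.4), and in Alc UA 3, Cd5l was 210.4 (nearest 59.4) and Hba-a1 334 (nearest 156). Ctrl 3 scored -7.77 on PC3 (nearest -0.25), and the mean log2(FPKM + 1) of the clock list was 2.51 in Ctrl 4 (nearest 2.72).

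In Alc against Ctrl the 11 tested genes that peak together with Dbp and the Per genes had a median log2 fold change of 1.76, and the 4 of the Arntl arm one of -1.13. All 17 clock genes called were called again without Ctrl 1 and Ctrl 5, so these libraries are not the cause. Every alcohol library lay above every control in 12 clock genes and below in 3, where chance gives 0.0666% of genes and 10.7% of all tested genes did so. Of 100 splits of the 10 libraries, 1, the real one, gave a mean for the list as large as 1.03 (highest other 0.67). That share speaks against chance for this list taken alone and was not adjusted for the 44 lists tested. Opposite movement of the arms is what another collection time could give, and an effect of the diet on the clock or on feeding time could give it too, so these cannot be told apart because diet and any difference in collection time coincide. The same limit applies to the other genes and lists that differed from Ctrl.

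Sinusoidal endothelial markers were lower in Alc than in Ctrl, and 2 of 100 splits gave a list mean as large as 1.22 in size (highest other 1.24). That share is under 0.05 for this list taken alone, without adjustment for the 44 lists tested, and 1 other split gave a larger mean. The endothelial minus Kupffer mean differed by -1.55 between Alc and Ctrl (two-sided exact permutation p = 0.0079). The difference was -1.48 without Ctrl 5 and -1.56 after quantile normalization (two-sided exact permutation p = 0.0079 and 0.0079). Camera did not call the Kupffer list itself in these 2 fits (camera adjusted p = 0.19 and 0.13). A lower share of all cells other than hepatocytes, alike in every type, would lower both lists alike if expression per cell were unchanged. The values argue against such a lower share on that condition only. Transcript levels cannot separate the number of cells from expression within them, so it is not excluded. The endothelial mean fell further than those of 7 of 12 other marker lists (unadjusted exact permutation p under 0.05) and of 8 after quantile normalization, 7 without Ctrl 5 and 5 without Ctrl 1 and Ctrl 5 (the last 2 with fewer assignments, 126 and 56), but in none of these 4 fits detectably further than those of T and NK, B and plasma, and erythroid cells (exact permutation p = 0.10 to 0.72), so a joint loss with these cells stays open. The list was called after quantile normalization (camera adjusted p = 1.3e-07 at the preset correlation; 2.0e-08 to 0.52 over all alternatives, the last with an estimated correlation). Camera compares a list with all other genes, so a lower scale of whole libraries could hardly have changed that call. The call therefore does not test a lower scale. The list median was -1.28 on the deposited scale, against -0.12 for all tested genes. A lower scale shared by all genes thus does not account for the whole fall. All 13 markers called were called again without Ctrl 1 and Ctrl 5. Fewer endothelial cells, lower transcription within them, and a difference in perfusion or sampling of the liver stay open and untested.

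Male-biased genes were higher in Alc UA than in Alc, and 1 of 100 splits, the real one, gave a list mean as large as 1.21 (highest other 1.06). That share speaks against chance for this list taken alone and was not adjusted for the 44 lists tested. Reads shared among Mup genes do not account for the rise alone, because the list without them was called (camera adjusted p = 0.024 with an estimated correlation). The list was also called without Alc 4 and Alc UA 2 (adjusted p = 0.033 with an estimated correlation), although 6 rather than 14 genes then passed adjusted over the list alone. Livers of female mice among the Alc libraries are excluded, since Ddx3y was at least 11.1 FPKM in each, against a mean of 14.1 in Alc UA. As a hypothesis, UA may have raised male-biased expression, with camera adjusted p = 0.024 for the list without Mup genes, found and tested on the same data.

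Counts of genes were set against the same splits. The real grouping called 3654 genes in Alc against Ctrl, as did 1 of 100 splits, the real one (highest other 2954), and 4673 in Alc UA against Ctrl, again 1 of 100 (highest other 2980), so chance is excluded for both. For Alc UA against Alc, 3 of 100 splits called at least 1 gene, the real one included, and 1 of the others called 4 (highest other 4). That share is under 0.05, but it rests on 1 gene and was not adjusted for the other split tests. The real count was 0 with the 2 groups alone, with the replicate block and without Alc 4 and Alc UA 2. Chance is therefore not excluded for this count. Splits cannot test the 0 genes moved back, because any split has at least 0 and so 100 of 100 matched it (highest other 1). The number of lists called by camera was often matched by other splits. As many as the 21 in Alc against Ctrl were called in 27 of 100 splits (highest other 27). For the 10 in Alc UA against Alc it was 88 (highest other 23), and for the 19 in Alc UA against Ctrl it was 38 (highest other 26). Splits that exchange few libraries keep part of a group difference, so a match alone does not show that these counts arose by chance. Most other splits of Alc and Alc UA nevertheless gave as many lists at the preset correlation. The number of lists called therefore does not set the real grouping apart, and the 10 calls are no evidence of an effect of UA.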

How the results depend on the processing

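Fits without Ctrl 1 and Ctrl 5 or without Alc 4 and Alc UA 2, and the male-biased list without the Mup genes, were chosen after seeing the data, and the other alternatives were planned. With 1 library left out the genes changed numbered 2571 to 4515 in Alc against Ctrl, 1 to 5 in Alc UA against Alc and 3835 to 5374 in Alc UA against Ctrl, and the genes moved back 0 to 4. In Alc against Ctrl 5870 genes changed with library weights and 353 with a log2 fold change over 1, which was 448 in Alc UA against Ctrl. In Alc UA against Alc the count was 2 with a mean of at least 5 FPKM, 2 with libraries scaled to the same sum, 3 with library weights, 0 with the replicate block, 0 with the 2 groups alone and 0 without Alc 4 and Alc UA 2. The genes moved back were 1 with a pseudocount of 0.1 (Mup5, which went past its Ctrl level). They were 1 with a mean of at least 5 FPKM and 1 with libraries scaled to the same sum. With library weights they were 2, and without Ctrl 1 and Ctrl 5 they were 1. Lists called fell to 1, 1 and 1 in the 3 comparisons with an estimated correlation, to 12, 1 and 9 with fry, and to 7 in Alc UA against Ctrl after quantile normalization. Fewer libraries, fewer genes or a wider spread enter some of these fits by construction, and otherwise the cause was not tested. Mice with the same replicate number did not pair, since 5 of 15 pairs had correlations of deviations over 0.1 (-0.30 to 0.29) and in 3 of 15 pairs the correlation exceeded those with other numbers. All 3 pairs of number 5 were over 0.1. The replicate block gave 3554 and 4534 genes in the comparisons with Ctrl. With it Plin2 in Alc against Ctrl and Fgf21 in Alc UA against Ctrl passed (adjusted p = 0.039 and 0.014), Mup5 in Alc UA against Alc and Cd5l in Alc UA against Ctrl did not (adjusted p = 0.052 and 0.063), and the calls of the other named genes were kept. For named genes, 1906 values with 1 library left out stayed called or stayed uncalled, 23 gained and 21 lost a call, and under other settings these were 1623, 35 and 11. Among values not called, 45 of genes and 174 of lists had the other sign. The absolute depth is unknown, so low genes cannot be weighed by their reads.

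With an estimated correlation, calls lost in Alc against Ctrl had adjusted p of 0.060 (P450s), 0.12 (female-biased), 0.16 (ethanol metabolism), 0.21 (glucose and glycogen), 0.29 (bile acid), 0.29 (one-carbon), 0.52 (acute phase), 0.52 (cholesterol), 0.52 (endothelial), 0.52 (male-biased), 0.53 (pericentral), 0.58 (fatty acid synthesis), 0.64 (AHR targets), 0.64 (B and plasma), 0.64 (NAD), 0.64 (T and NK), 0.64 (amino acid), 0.64 (erythroid), 0.84 (Kupffer), 0.90 (ribosomal). With an estimated correlation, calls lost in Alc UA against Alc had adjusted p of 0.84 (female-biased), 0.84 (retinol), 0.85 (P450s), 0.85 (cholesterol), 0.85 (endothelial), 0.85 (fatty acid oxidation), 0.85 (immediate-early), 0.85 (oxidative phosphorylation), 0.88 (inflammatory cytokines). With an estimated correlation, calls lost in Alc UA against Ctrl had adjusted p of 0.24 (P450s), 0.35 (bile acid), 0.35 (ethanol metabolism), 0.35 (female-biased), 0.35 (glucose and glycogen), 0.37 (acute phase), 0.37 (one-carbon), 0.49 (endothelial), 0.49 (pericentral), 0.52 (AHR targets), 0.64 (ER stress), 0.90 (Kupffer), 0.90 (amino acid), 0.90 (cholesterol), 0.90 (fatty acid oxidation), 0.90 (fatty acid synthesis), 0.96 (ribosomal), 0.98 (oxidative phosphorylation). With fry, calls gained in Alc against Ctrl had adjusted p of 0.036 (platelet). With fry, calls lost in Alc against Ctrl had adjusted p of 0.052 (cholesterol), 0.070 (one-carbon), 0.070 (pericentral), 0.11 (ribosomal), 0.14 (fatty acid synthesis), 0.19 (acute phase), 0.20 (AHR targets), 0.26 (amino acid), 0.37 (NAD), 0.46 (Kupffer). With fry, calls lost in Alc UA against Alc had adjusted p of 0.22 (female-biased), 0.22 (retinol), 0.63 (P450s), 0.63 (cholesterol), 0.63 (oxidative phosphorylation), 0.69 (endothelial), 0.89 (fatty acid oxidation), 0.89 (immediate-early), 0.89 (inflammatory cytokines). With fry, calls gained in Alc UA against Ctrl had adjusted p of 0.0062 (erythroid), 0.041 (B and plasma), 0.048 (retinol). With fry, calls lost in Alc UA against Ctrl had adjusted p of 0.051 (bile acid), 0.051 (pericentral), 0.051 (ribosomal), 0.10 (glucose and glycogen), 0.13 (AHR targets), 0.27 (acute phase), 0.38 (Kupffer), 0.38 (one-carbon), 0.51 (ER stress), 0.56 (fatty acid oxidation), 0.57 (amino acid), 0.57 (cholesterol), 0.60 (fatty acid synthesis). After quantile normalization, calls lost in Alc against Ctrl had adjusted p of 0.052 (fatty acid synthesis), 0.057 (one-carbon), 0.13 (Kupffer), 0.14 (NAD), 0.17 (AHR targets), 0.20 (acute phase). After quantile normalization, calls gained in Alc UA against Alc had adjusted p of 0.0044 (hepatocyte). After quantile normalization, calls lost in Alc UA against Ctrl had adjusted p of 0.077 (glucose and glycogen), 0.079 (Kupffer), 0.079 (bile acid), 0.12 (female-biased), 0.12 (AHR targets), 0.12 (amino acid), 0.13 (fatty acid oxidation), 0.14 (cholesterol), 0.15 (one-carbon), 0.15 (ER stress), 0.24 (fatty acid synthesis), 0.25 (acute phase). With a pseudocount of 0.1, calls lost in Alc against Ctrl had adjusted p of 0.052 (B and plasma), 0.052 (erythroid), 0.055 (AHR targets), 0.056 (NAD), 0.073 (T and NK). With a pseudocount of 0.1, calls lost in Alc UA against Alc had adjusted p of 0.053 (P450s). Without Ctrl 1 and Ctrl 5, calls gained in Alc against Ctrl had adjusted p of 0.014 (ER stress). Without Ctrl 1 and Ctrl 5, calls lost in Alc against Ctrl had adjusted p of 0.071 (NAD), 0.15 (erythroid). Without Ctrl 1 and Ctrl 5, calls gained in Alc UA against Ctrl had adjusted p of 0.048 (T and NK). Without Ctrl 1 and Ctrl 5, calls lost in Alc UA against Ctrl had adjusted p of 0.079 (oxidative phosphorylation). Without Alc 4 and Alc UA 2, calls gained in Alc UA against Alc had adjusted p of 4.6e-04 (Kupffer), 0.0027 (amino acid), 0.0092 (lipid droplet), 0.026 (B and plasma), 0.029 (ER stress), 0.042 (neutrophil). Without Alc 4 and Alc UA 2, calls lost in Alc UA against Alc had adjusted p of 0.075 (female-biased). With the replicate block, calls lost in Alc against Ctrl had adjusted p of 0.054 (NAD). With 1 library left out, lists whose call changed in Alc against Ctrl had adjusted p of 0.049 to 0.82 (fatty acid oxidation), 0.018 to 0.13 (acute phase), 0.0084 to 0.29 (ER stress), 0.019 to 0.10 (NAD), 0.018 to 0.14 (AHR targets), 1.3e-04 to 0.087 (ribosomal), 0.0033 to 0.19 (Kupffer), 0.0084 to 0.087 (T and NK), 0.010 to 0.079 (B and plasma), 0.0056 to 0.13 (erythroid). With 1 library left out, lists whose call changed in Alc UA against Alc had adjusted p of 5.7e-05 to 0.23 (P450s), 1.0e-04 to 0.63 (fatty acid synthesis), 4.1e-10 to 0.059 (fatty acid oxidation), 0.0020 to 0.94 (lipid droplet), 0.040 to 0.96 (acute phase), 1.6e-06 to 0.96 (interferon), 0.016 to 0.76 (ER stress), 0.026 to 1.0 (extracellular matrix), 1.1e-04 to 0.10 (female-biased), 7.9e-04 to 0.96 (amino acid), 0.0082 to 0.55 (pericentral), 1.9e-04 to 0.76 (Kupffer), 0.026 to 0.33 (neutrophil). With 1 library left out, lists whose call changed in Alc UA against Ctrl had adjusted p of 0.0047 to 0.10 (fatty acid synthesis), 0.0040 to 0.12 (cholesterol), 0.0029 to 0.10 (fatty acid oxidation), 0.0058 to 0.074 (acute phase), 0.0018 to 0.10 (ER stress), 0.0019 to 0.11 (oxidative phosphorylation), 0.0012 to 0.071 (amino acid), 0.0042 to 0.056 (AHR targets), 2.2e-04 to 0.054 (ribosomal), 4.7e-04 to 0.0504 (Kupffer), 0.0499 to 0.39 (T and NK), 0.018 to 0.24 (B and plasma), 0.014 to 0.18 (erythroid). The extracellular matrix list in Alc UA against Alc, not called with all libraries, was called in the opposite direction without Alc UA 2 (adjusted p = 0.026).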

Other observations

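Lists described here were fixed before the data were examined and were not called by camera. They, the Y-linked genes and Npas2 were picked for description after their values were seen. In Alc against Ctrl, of 25 p53 target and cell death genes, 2 rose and 10 fell over all genes tested, against 3 and 10 adjusted over the list alone and 3 and 8 with median-of-ratios size factors (median -0.07 relative to all genes; camera adjusted p = 0.58). Of 24 immediate-early and dissociation stress genes, 0 rose and 8 fell over all genes tested, against 0 and 8 adjusted over the list alone and 0 and 6 with median-of-ratios size factors (median -0.37 relative to all genes; camera adjusted p = 0.21). In Alc UA against Ctrl, of 33 interferon-stimulated genes, 0 rose and 8 fell over all genes tested, against 0 and 7 adjusted over the list alone and 3 and 3 with median-of-ratios size factors (median -0.14 relative to all genes; camera adjusted p = 0.93). Of 21 retinol metabolism genes, 2 rose and 7 fell over all genes tested, against 2 and 7 adjusted over the list alone and 4 and 5 with median-of-ratios size factors (median -0.01 relative to all genes; camera adjusted p = 0.95).

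The Y-linked gene Eif2s3y was 44.8 ± 4.77 FPKM in Ctrl, 33.8 ± 2.78 in Alc and 28.9 ± 3.89 in Alc UA (SD, n = 5; limma adjusted p = 0.0099 for Alc and 4.1e-04 for Alc UA against Ctrl). Ddx3y was 12.4 ± 1.15, 12.5 ± 1.24 and 14.1 ± 2.47 (adjusted p = 0.97 and 0.28). Kdm5d was 3.56 ± 0.465, 3.01 ± 0.448 and 2.73 ± 0.376 (adjusted p = 0.17 and 0.033). Uty was 5.71 ± 0.955, 5.09 ± 0.624 and 4.45 ± 0.329 (adjusted p = 0.32 and 0.030). Npas2, which encodes a partner of BMAL1 and was too low to be tested, was 1.5 ± 0.648 in Ctrl, 0.0640 ± 0.0451 in Alc and 0.0340 ± 0.00548 in Alc UA.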
